A study of Homo sapiens with 4 samples.

How the data were processed

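RNA from SH-SY5Y neuroblastoma cells was measured on 4 Affymetrix arrays, 2 from cells transfected with a control siRNA and 2 from cells transfected with an siRNA against LSD1. Per the labels' protocols, total RNA was purified on columns, labelled with biotin and hybridized as the array's manufacturer recommends. Groups and replicate numbers were taken from the sample titles. The series' design text describes 2 separate transfections per siRNA, so the p-values measure the spread between transfections of 1 cell line. The title of siLSD1 replicate 2 abbreviates the target's name without its number, and the array was placed in the siLSD1 group on that title.

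The deposited values were 1 number per probe set and array on a log2 scale. The scale is not given in the sources used here and was found from the values. The base-2 antilogs had a mean of 100.0 on each array after the lowest and highest 2% of probe sets were left out, as a scaling of each array to one common level gives, whereas base-e antilogs had means from 1408 to 1449. The summary method and the software that the authors used to make the values are not given in the sources used here. Array medians of the deposited log2 values were 4.27 and 4.17 for siControl and 4.09 and 4.01 for siLSD1. Their range of 0.27 exceeded the tolerance of 0.25 set before the data were examined, so the arrays were quantile normalized, and the deposited scaling became an alternative. Quantile normalization gives every array the same distribution and would remove a difference in overall signal between the groups. No 2 arrays held identical values.

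Probe sets were named through the platform's annotation of 2016. Of 54675 probe sets, 62 were controls. Apart from controls, 41091 had 1 gene symbol and 1801 had several. A further 11777, some of the controls among them, had none in the table used. Only those with 1 symbol were named. Symbols were checked through the Entrez gene identifier against RefSeq gene names for the assembly GRCh38.p14, where 41043 of the 1-symbol probe sets matched. Of these, 0 symbols needed a change, so the table used already held the RefSeq symbols. No genome coordinates are printed. Each gene was represented by its probe set with the highest mean over the 4 arrays. Of 19775 genes, the 7910 whose mean lay below the 40th percentile (4.12) were left out, and 11865 were tested.

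Groups were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a mean-variance trend, a two-sided test without a replicate term, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The moderated test had 8.22 degrees of freedom, most of them borrowed from the other genes. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333. The number of arrays limits the precision. The fit was tested on simulated data with the real genes' means and 200 changed genes in each of 20 simulations. Spreads were drawn from limma's fitted variance prior, genes were independent and no array stood apart, which is an easier setting than the real arrays. The fit recovered 25.7% of 2-fold, 81.3% of 4-fold and 93.3% of 8-fold changes, with 4.81% false calls. The 25 genes of the TGF-beta list, shifted by 0.5, were called in all 20 simulations. The real list had a median of 0.21 and an estimated correlation of 0.19, so this result does not carry over to it.

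The 25 gene lists were fixed before the data were examined. They covered the LSD1-CoREST complex, other histone lysine demethylases, REST-repressed genes, neuronal differentiation, noradrenergic identity, the mesenchymal neuroblastoma state, S-phase, G2 and mitosis, p53 targets, the BCL2 family, interferon-stimulated genes, SNAI1-regulated epithelial genes, TGF-beta signalling, the Notch pathway, MYC targets, hypoxia, endoplasmic reticulum stress, cholesterol synthesis, the respiratory chain, immediate-early genes, axon guidance, Schwann and glial markers, fibroblast markers, blood cell markers and housekeeping genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry tests whether the list itself moves, in one direction or in either.

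The genes named in the text were chosen by a rule written before the data were examined. KDM1A came first. For each direction, 12 places went to genes past the threshold with both siLSD1 arrays on one side of both siControl arrays. Places left open went to genes that did not pass, with at least a 2-fold difference and groups that did not overlap, in order of the unadjusted p. Genes without an official symbol were skipped as far as the form of the name showed it (LOC, open reading frame, LINC, clone and antisense names). In each list up to 4 members with the smallest unadjusted p could be named, or those with the highest mean level for markers of other cell types.

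Alternatives set before the data were examined were the deposited scaling, median centring of each array, no filter or a 60th percentile filter, the mean of all probe sets of a gene or every probe set by itself, a variance prior without trend or with robust estimation, a replicate block, leaving out each array in turn, other thresholds and the other list tests. Array weights, leaving out both arrays that stood apart, and the LSD1-CoREST list without KDM1A were added after seeing the data. Control probe sets were used only to describe the quality of the arrays, on the deposited scale.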

Results

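Transcript levels were measured in SH-SY5Y cells, a human neuroblastoma line of neuronal character that grows in culture. The cells had received a small interfering RNA (siRNA) against LSD1, a demethylase of histone lysines that is encoded by KDM1A, or a control siRNA. Each group consisted of 2 arrays, called siControl and siLSD1 below, and the submitters' design text describes the transfections of a group as separate experiments. Total RNA was hybridized to Affymetrix arrays with 54675 probe sets. Gene symbols were available for 19775 genes, of which 11865 were bright enough to be tested. The number of arrays limited the precision, and the 95% interval of a fold change had a median half-width of 0.58 on the log2 scale, or 1.5-fold. All gene levels are log2 signals after quantile normalization, unless another scaling is named, and levels of control probe sets are deposited log2 signals. All fold changes are siLSD1 relative to siControl.

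The comparison addressed which transcripts differ in level when LSD1 is knocked down in neuroblastoma cells. KDM1A, the target of the siRNA, fell to 40.04% of its control level. Its signal, from the only probe set that named KDM1A alone, was 9.79 and 9.78 on the siControl arrays and 8.40 and 8.54 on the siLSD1 arrays. The group means were 9.79 ± 0.0057 and 8.47 ± 0.10 (SD, n = 2), which gave a log2 fold change of -1.32 with a 95% interval from -1.69 to -0.95. The transcript was thus 2.50-fold lower, with limits of 1.93-fold and 3.23-fold, and both siLSD1 arrays lay below both siControl arrays. In limma's moderated test the adjusted p was 0.000558 when adjusted over the list alone, that is over the 17 tested members of the LSD1-CoREST list that held KDM1A. Over all 11865 genes KDM1A had the smallest p of any gene (3.28e-05 in limma), and its adjusted p of 0.39 did not pass the threshold of 0.05.

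No gene, the targeted one included, could be called over all genes with all 4 arrays and no replicate term. In limma 0 genes were higher and 0 were lower at an adjusted p under 0.05, and the second smallest adjusted p was 0.9996. At an unadjusted p under 0.05, limma gave 272 higher and 137 lower genes, 409 in all, against 593 expected by chance. Both siLSD1 arrays lay on one side of both siControl arrays for 31.7% of the genes, where chance gives 33.3%. Among these, 75 genes were at least 2-fold higher and 40 at least 2-fold lower. Simulated data of the same size had independent genes and no array that stood apart. In them limma recovered 25.7% of 2-fold changes, 81.3% of 4-fold changes and 93.3% of 8-fold changes. Many 2-fold changes were thus not detectable with this number of arrays, even in that easier setting. Of the 272 genes that were higher at an unadjusted p under 0.05 in limma, 217 had their lowest value on siControl replicate 1, an array that stood apart from the other 3.

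The genes with the smallest p among those at least 2-fold higher did not pass the threshold, and their levels are given as measured. ISLR2, a membrane protein of developing neurons, had a signal of 5.74 ± 0.07 in siControl and 7.37 ± 0.54 in siLSD1 cells (SD, n = 2), a 3.09-fold difference with a 95% interval from 0.91 to 2.35 on the log2 scale. GSR, the glutathione reductase, was at 6.80 ± 0.65 and 8.06 ± 0.06, or 2.40-fold higher. PLEKHA2, an adaptor that binds phosphoinositides, was 2.43-fold higher, and IQGAP2, a scaffold protein of the cytoskeleton, 2.45-fold. CENPT, a protein of the kinetochore, was 2.46-fold higher, PEPD, a dipeptidase that acts on proline, 2.40-fold and PRR36 3.64-fold. RPS6KA6, a kinase of the ribosomal protein S6 kinase family, was 2.03-fold higher, PAK1IP1, an inhibitor of the kinase PAK1, 2.01-fold and TFR2, a transferrin receptor, 2.01-fold. EIF3C, a subunit of a translation initiation factor with a near-identical gene copy, was 2.13-fold higher. HCRP1 was 2.52-fold higher, but this record had no gene type in the RefSeq names used and may lack an official symbol. PRR36, HCRP1, CENPT and IQGAP2 had at least 1 siControl value below the filter level of 4.12, so the size of these differences is uncertain. Limma's unadjusted p for these 12 genes ran from 0.000730 to 0.0114, and the adjusted p was 0.9996 for each. In 10 of the 12 the siControl replicate 1 value was the lower of the control values, and without that array the median log2 fold change of the 12 was 0.87 in place of 1.27 and 9 of the 12 were less than 2-fold higher. In proportion, the largest moves were in GSR (1.26 to 0.80), PEPD (1.26 to 0.61), PAK1IP1 (1.01 to 0.57) and RPS6KA6 (1.02 to 0.64). Other probe sets above the filter were present for 4 of these genes, and 2 of those 5 probe sets were higher as well. The only other probe set of GSR was not higher, nor was that of TFR2, while that of HCRP1 and 1 of the 2 of RPS6KA6 were.

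The genes with the smallest p among those at least 2-fold lower did not pass the threshold either. VHL, the substrate-binding subunit of the ubiquitin ligase that marks hypoxia-inducible factors, had a signal of 7.45 ± 0.31 in siControl and 5.64 ± 0.32 in siLSD1 cells (SD, n = 2). This was a 3.497-fold difference, with a 95% interval from -2.48 to -1.14 on the log2 scale. GNL3L, a nucleolar GTPase, was at 7.21 ± 1.03 and 5.14 ± 0.17, or 4.20-fold lower, and both of its other probe sets above the filter were lower too. GNAO1, the alpha subunit of a G protein abundant in neurons, was 2.00-fold lower by its brightest probe set, while its other 2 probe sets above the filter were higher. AVIL, an actin-binding protein, was 3.13-fold lower and CHRNA2, a nicotinic acetylcholine receptor subunit, 2.22-fold lower. RAB4B, a small GTPase of endosomes, was 4.36-fold, CEACAM19 3.64-fold, GVQW3 2.85-fold and the non-coding RNA NEK2-DT 2.08-fold lower. RAB4B, CEACAM19, GVQW3 and CHRNA2 had at least 1 siLSD1 value below the filter level of 4.12, so the size of these differences is uncertain. The transcribed pseudogenes BMS1P1 (2.44-fold), BMS1P2 (2.37-fold) and SMG1P5 (2.02-fold) were also lower, and their probes may cross-hybridize with related copies, so that these 3 values are uncertain. The same holds for AVIL and NEK2-DT, whose probe sets are of the type that shares probes with other sequences. The log2 fold change of GNL3L was -1.34 without siControl replicate 2 in place of -2.07, and that of GVQW3 was -0.91 without siLSD1 replicate 1 in place of -1.51. Limma's unadjusted p for these 12 genes ran from 0.000237 to 0.0131, with an adjusted p of 0.9996 for each.

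**Figure D1:**
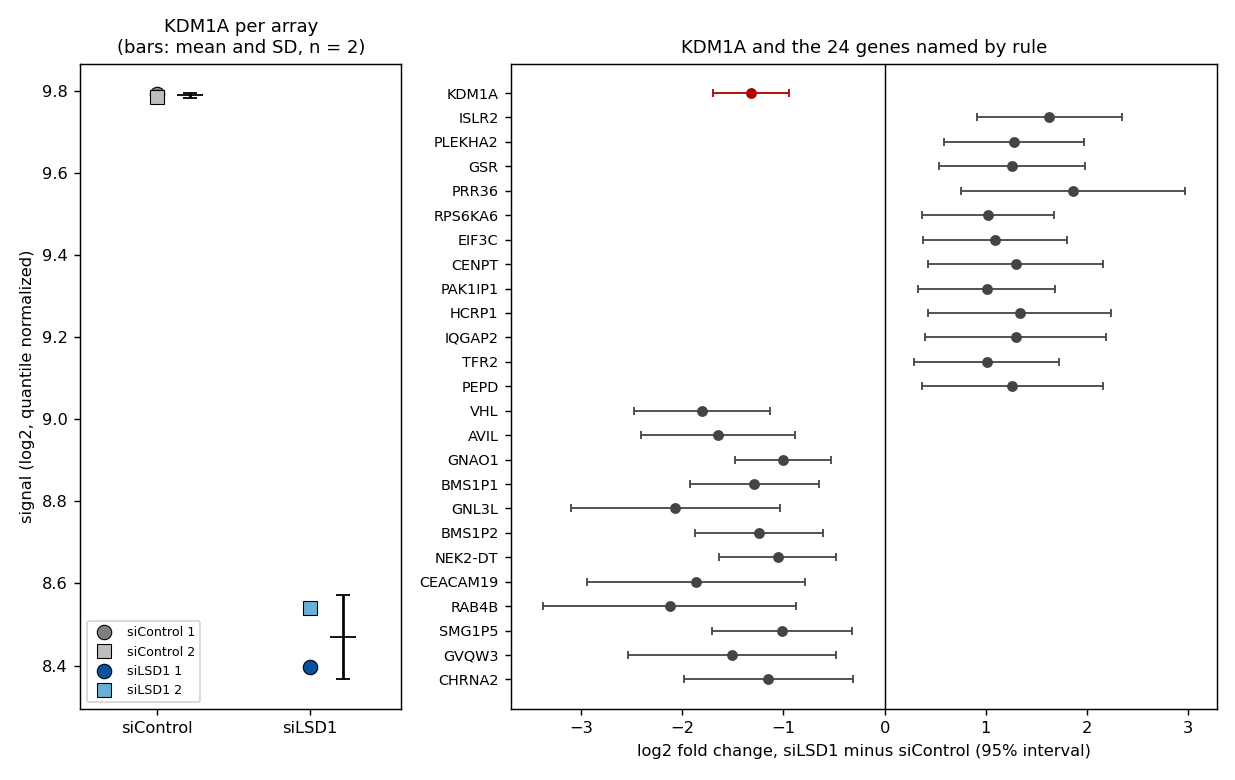
Left, KDM1A signal on each of the 4 arrays (log2, points), with the group mean and SD beside the points. Right, log2 fold change (siLSD1 minus siControl) with 95% intervals for KDM1A and the 24 genes chosen by rule. KDM1A lay at 9.79 and 9.78 on the siControl arrays and at 8.40 and 8.54 on the siLSD1 arrays. Neither KDM1A (adjusted p = 0.39 in limma) nor any of the 24 other genes passed the adjusted threshold over all genes.

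Gene lists fixed in advance were then compared as groups. Of 25 lists, 23 had at least 5 tested members, and their 515 distinct members included 1 gene, KDM1A, that passed when adjusted over the list alone, and 0 genes that passed over all genes tested. With limma's camera test and a preset correlation between genes, 2 lists were higher after LSD1 siRNA and 0 were lower. With an estimated correlation camera called 0 lists, and so did limma's fry for changes in one direction. Leaving out 1 array turned the sign of the median in 13 of the 21 lists without a call, and turned or moved it by over 1.5 times in 19 of them. The same step moved the log2 fold change by over 1.5 times, or turned it, for 67 of the 95 members named by rule apart from KDM1A, 46 of them without siControl replicate 1. Median centring shifted every log2 fold change by the same -0.0756 from the deposited scaling, so that a turn under median centring says nothing about a list by itself.

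Genes of the mesenchymal neuroblastoma state, the program of substrate-adherent cells, were higher as a group. Of 22 tested members, 18 had a higher and 4 a lower mean in siLSD1 cells, with a median log2 fold change of 0.26 (camera adjusted p = 0.00135). With an estimated correlation the adjusted p was 0.825. TWIST1, a transcription factor of the mesenchyme, had a log2 fold change of 1.09, but its siControl replicate 1 value of 9.32 was far from the 11.06 of the other control array. CCN1, a matrix protein, had a log2 fold change of 0.83, ANXA2, a membrane-binding annexin, 0.39 and VIM, the intermediate filament vimentin, 0.18, none of them past the threshold. The members' median deviation from each gene's mean was 0.10 and -0.32 on the siControl arrays and 0.08 and 0.22 on the siLSD1 arrays. The control arrays thus differed, with siControl replicate 2 the lowest of the 4 arrays and siControl replicate 1 between the siLSD1 arrays. The list median was 0.46 without siControl replicate 1, where the call held, and 0.09 without siControl replicate 2, where it was lost. Under median centring it was 0.12 (camera adjusted p = 0.00601).

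Members of TGF-beta signalling were higher as well. Of 25 tested members, 21 were higher and 4 lower, with a median log2 fold change of 0.21 (camera adjusted p = 0.00744, and adjusted p = 0.825 with an estimated correlation). ID2 (0.43), ID1 (0.60) and ID4 (0.98), inhibitors of basic helix-loop-helix transcription factors that respond to BMP signals, had the smallest p of the list, followed by the BMP and activin pseudoreceptor BAMBI (0.48). None of them passed the threshold. The median was 0.29 without siControl replicate 1, where the call held. It was 0.08 without siControl replicate 2 and 0.13 without siLSD1 replicate 2, and both times the call was lost. The call was also lost without a filter (0.16, adjusted p = 0.0969), with the mean of all probe sets (0.16, adjusted p = 0.1) and with every probe set by itself (0.16, adjusted p = 0.0599). The array siLSD1 replicate 2 also had the strongest ribosomal RNA signal of the series.

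**Figure D2:**
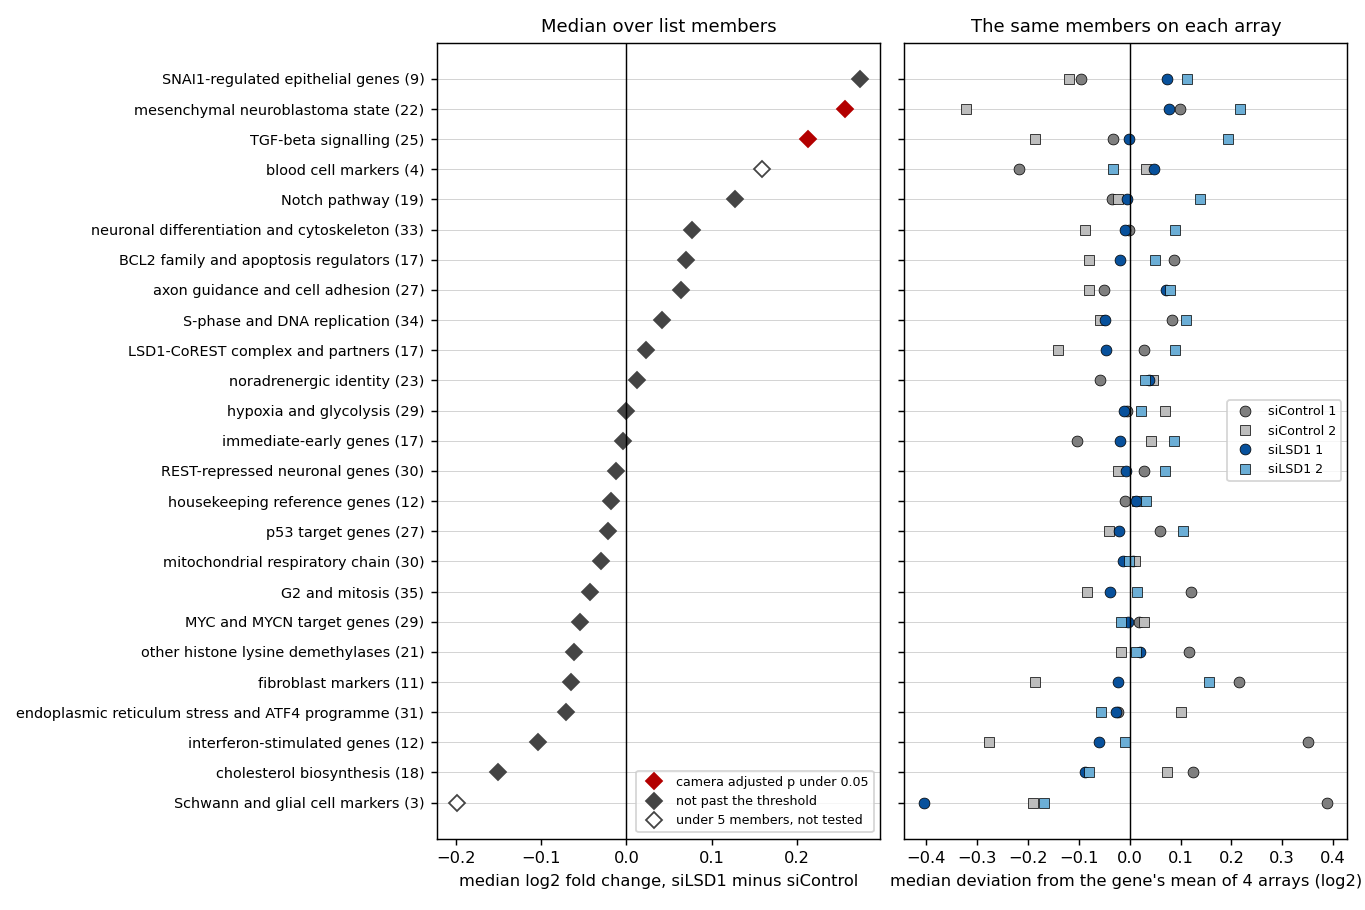
Left, median log2 fold change (siLSD1 minus siControl) over the tested members of each of the 25 lists, with the number of tested members in parentheses. Right, the median deviation of the same members from each gene's mean over the 4 arrays, on each array (log2). The mesenchymal list (0.26) and the TGF-beta list (0.21) passed camera's threshold, and in both siControl replicate 2 was the lowest array. They did not pass camera with an estimated correlation (adjusted p = 0.825 for both), a test with little power for 4 arrays.

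Neuronal programs did not pass the test. Among 33 tested genes of neuronal differentiation and the neuronal cytoskeleton, 20 were higher and 13 lower, with a median log2 fold change of 0.08 (camera adjusted p = 0.463) that was 0.02 without siControl replicate 2 and 0.02 without siLSD1 replicate 2. The receptor tyrosine kinase RET (0.45), the microtubule-associated proteins MAP2 (0.33) and MAP1B (0.25) and the neurofilament gene NEFL (0.47) were higher on both siLSD1 arrays than on both siControl arrays, at an adjusted p of 0.355 over the list alone in limma. These were the list's members with the smallest p, so their separation follows largely from how they were picked. Of 23 noradrenergic identity genes, 13 were higher and 10 lower, and the median of 0.01 turned to -0.02 under the deposited scaling and to -0.10 under median centring (camera adjusted p = 0.479). SLC6A2, the noradrenaline transporter, was 1.49-fold higher (adjusted p = 0.101 over the list alone in limma), SOX11 had a log2 fold change of 0.23 and HAND1 of -0.23. REST-repressed neuronal genes were split into 15 higher and 15 lower members, with a median of -0.01 that turned to 0.04 under the deposited scaling, a mean of 0.06 and an upward test (adjusted p = 0.908). Their members with the smallest p were CHRNB2 (0.90), VGF (0.43) and BEX1 (-0.13). Axon guidance and cell adhesion genes included 19 higher and 8 lower members, with a median of 0.06 that turned to -0.03 under median centring and a mean of 0.24 (camera adjusted p = 0.18). Of these, the ephrin EFNA1 had a log2 fold change of 1.13, the semaphorin SEMA3C of 0.57 and the netrin receptor UNC5B of 1.05. The groups of UNC5B overlapped. Its value was 0.31 without siControl replicate 1 and turned to -0.14 without both that array and siLSD1 replicate 2. Without siLSD1 replicate 2 the axon guidance list was called higher, with a median of 0.11 (adjusted p = 0.0149).

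Chromatin regulators other than the target did not stand apart. In the LSD1-CoREST list, 10 of 17 tested members were higher and 7 lower, with a median of 0.02 (-0.05 under median centring), a mean of -0.0086 and a downward camera test (adjusted p = 0.769). Fry for changes in either direction gave an adjusted p of 0.0068 with KDM1A and 0.931 for the 16 members without it. Its other members with the smallest p were CTBP2 (0.15), SNAI1 (0.57) and PHF21A (0.32). Of 21 other histone lysine demethylases, 9 were higher and 12 lower, with a median of -0.06, a mean of 0.06 and an upward test (adjusted p = 0.769). KDM5A had a log2 fold change of 0.52, PHF8 of 0.75 and KDM2B of 0.38.

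Cell cycle and cell death genes did not pass the test. Of 34 S-phase genes, 21 were higher and 13 lower, with a median of 0.04 that turned to -0.05 under median centring (adjusted p = 0.668), and of 35 genes of G2 and mitosis 13 were higher and 22 lower, with a median of -0.04 (adjusted p = 0.477). Examples were the DNA ligase LIG1 (0.52) and the ribonucleotide reductase subunit RRM2 (0.26), and in mitosis the centromeric histone CENPA (-0.42) and CDK1 (0.41). Among 27 p53 target genes, 13 were higher and 14 lower, with a median of -0.02, a mean of 0.04 and an upward test (adjusted p = 0.769). CDKN1A, the cyclin-dependent kinase inhibitor p21, was 1.62-fold higher (adjusted p = 0.542 over the list alone in limma), TNFRSF10B had a log2 fold change of 0.39 and MDM2 of 0.38. Of 17 BCL2 family genes and other regulators of apoptosis, 12 were higher and 5 lower, with a median of 0.07 (adjusted p = 0.672), among them the survival gene MCL1 (0.19) and the initiator caspase CASP9 (-0.52).

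Signalling and stress programs gave no further call. Among 19 Notch pathway genes, 12 were higher and 7 lower, with a median of 0.13 that turned to -0.01 under median centring (adjusted p = 0.479), and the members included DLK1 (-0.23), DTX3 (0.71) and NOTCH3 (0.46). Of 17 immediate-early genes, 8 were higher and 9 lower, with a median of -0.0043 that turned to 0.01 under the deposited scaling, a mean of 0.06 and an upward test (adjusted p = 0.769), and JUN (0.66) and DUSP1 (-0.47) lay on opposite sides. Interferon-stimulated genes numbered 5 higher and 7 lower of 12, with a median of -0.10 (adjusted p = 0.668) that turned to 0.23 without siControl replicate 1 and was -0.34 without siControl replicate 2, with IFIT5 at 0.63 and USP18 at -0.89. Of 9 SNAI1-regulated epithelial genes, 6 were higher and 3 lower, with a median of 0.27 and a mean of 0.04 (adjusted p = 0.769). The median was 0.03 without siControl replicate 1, 0.02 without siLSD1 replicate 2, 0.03 under median centring, 0.04 without a filter and 0.02 with every probe set by itself, and the tight junction gene TJP1 (0.36) and the keratin KRT7 (-0.84) differed in direction.

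Metabolic and growth programs had medians near or below 0. Of 18 cholesterol biosynthesis genes, 7 were higher and 11 lower, with a median of -0.15 (camera adjusted p = 0.18), including EBP (-0.41) and the squalene epoxidase SQLE (-0.33). Of 31 genes of endoplasmic reticulum stress and the ATF4 program, 10 were higher and 21 lower, with a median of -0.07 (adjusted p = 0.18), including DDIT4 (-0.80) and the chaperones HSP90B1 (-0.36) and HSPA5 (-0.30). MYC and MYCN target genes were higher in 10 and lower in 19 of 29 cases, with a median of -0.05, a mean of 0.0051 and a downward test (adjusted p = 0.344), including the methyltransferase PRMT1 (-0.33) and the chaperonin HSPE1 (-0.22). Of 29 genes of hypoxia and glycolysis 15 were higher and 14 lower, with a median of 2.6e-05 that turned to -0.05 under the deposited scaling, a mean of -0.03 and a downward test (adjusted p = 0.477), including the aldolase ALDOC (-0.78) and TPI1 (-0.19). Without siControl replicate 1, the MYC, hypoxia, endoplasmic reticulum stress and cholesterol lists were called lower, with medians of -0.05, -0.08, -0.12 and -0.17 and adjusted p values of 0.0328, 0.0366, 0.0005 and 0.00619. Mitochondrial respiratory chain genes were higher in 12 and lower in 18 of 30 cases, with a median of -0.03 (adjusted p = 0.463), including CYC1 (-0.41) and SDHC (-0.49). Of 12 housekeeping reference genes 5 were higher and 7 lower, with a median of -0.02, a mean of 0.04 and an upward test (adjusted p = 0.769), and ACTB had a log2 fold change of 0.17.

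Markers of other cell types were measured beside these lists. Of 11 tested fibroblast markers, 5 were higher and 6 lower, with a median of -0.06, a mean of 0.12 and an upward test (camera adjusted p = 0.477), and MMP2 (10.2), FBLN1 (8.79), COL3A1 (8.76) and LUM (7.42) had the highest mean levels. The sign of this median was not stable. It turned to 0.19 without siControl replicate 1 (adjusted p = 0.0292), 0.20 without siLSD1 replicate 1, 0.13 without a filter or with the 60th percentile filter, 0.23 with the mean of all probe sets and 0.14 with every probe set by itself. Their deviations were 0.22 and -0.19 on the siControl arrays and -0.02 and 0.16 on the siLSD1 arrays, so that siControl replicate 2 was the lowest array for these markers, as it was for the mesenchymal list, which holds 3 of the same genes. Among Schwann and glial markers only CNP (7.71), GAS6 (7.50) and EDNRB (4.29) were bright enough to test, with 1 higher and 2 lower and a median of -0.20, and among blood cell markers only CD79A (5.71), CD8A (5.16), LCP1 (4.70) and HBB (4.44), with 3 higher and 1 lower and a median of 0.16. These lists were too short for a test.

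The arrays themselves differed in ways that the groups did not account for. Over the tested genes, siControl replicate 1 had correlations of 0.956 to 0.960 with the other arrays, while the other 3 arrays had correlations of 0.979 to 0.980 with one another. These correlations are across genes, which are not independent replicates. On siControl replicate 1, 112 genes lay at least 2.83-fold below the other 3 arrays where those 3 were close together, among them RARS1 (7.30 against 10.8 to 10.9) and USP48 (5.26 against 8.95 to 9.19), which were named after their values were seen. The same count was 6 on siControl replicate 2, 14 on siLSD1 replicate 1 and 8 on siLSD1 replicate 2. The array siLSD1 replicate 2 had a mean 18S ribosomal RNA control signal of 10.54, against 5.49, 5.79 and 5.96 on the other arrays, and its 5′ control probe sets were dimmer relative to the 3′ ones.

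**Figure D3:**
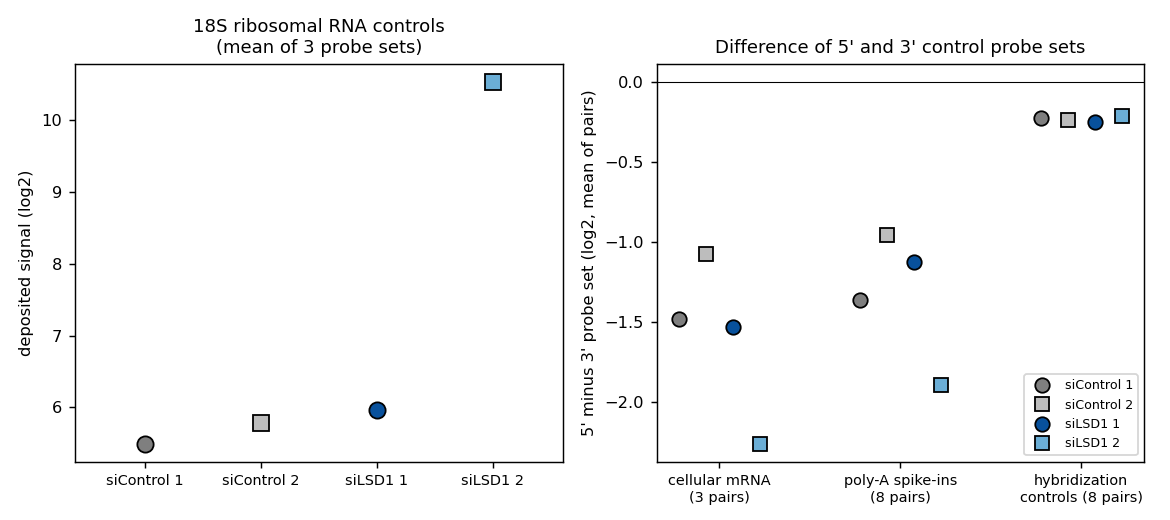
Left, mean deposited signal (log2) of the 3 control probe sets for 18S ribosomal RNA on each array. Right, mean difference between the 5′ and 3′ probe sets (log2) of cellular mRNA controls, bacterial poly-A spike-ins and hybridization controls on each array. The array siLSD1 replicate 2 was highest for 18S RNA (10.54) and lowest for the cellular and spike-in differences (-2.26 and -1.89), while the hybridization controls lay between -0.25 and -0.21 on all 4 arrays.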

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

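The tests on the control probe sets of siLSD1 replicate 2 were chosen after the values were seen, as were the check of bright probe sets on siControl replicate 1 and the curve fitted to its deposited values. The other tests on siControl replicate 1 were set out before their results were seen.

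A strong signal appeared in control probe sets that no comparison used. The 18S ribosomal RNA probe sets of siLSD1 replicate 2 had a mean of 10.54, which was 4.75 above the higher siControl array on the log2 scale and 27.7-fold above the mean of the other 3 arrays. On the same array the 5′ probe sets of the bacterial poly-A spike-ins were dimmer relative to the 3′ ones, with a mean difference of -1.89 against -1.15 ± 0.20 (SD) on the other 3 arrays. Degradation of the cells' RNA before the spike-ins were added cannot account for the spike-ins, which deviated by -0.74, in 6 of 8 pairs beyond all other arrays. Several pairs measure the same spike-in RNA and are not independent. The 3 cellular controls deviated by a mean of -0.90, mostly through 1 pair at -1.86, while the others were at -0.51 and -0.31. Degradation of the cells' RNA in addition is not excluded. Shortened products of the labelling reaction may be the cause of the low 5′ signal. The hybridization controls, which are added already labelled, deviated by only 0.0246. The source of the ribosomal RNA signal, biological or technical, was not tested.

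The array siControl replicate 1 stood apart from the other 3, with 112 genes at least 2.83-fold below them and 12 at least 2.83-fold above. Fewer transcripts of these genes in that sample are argued against by their other probe sets, which deviated by a median of -0.0893 (95% bootstrap interval -0.18 to 0.19, 48 genes), while the probe sets of these genes that stood out deviated by -1.76. In 8 of the 48 genes the other probe sets lay below -0.5. Many of the other probe sets were dim, but 43 bright probe sets had a second bright probe set of the gene. There the medians were -1.79 and 0.087 (interval -0.032 to 0.14), and in 3 of the 43 the second lay below -0.5. USP48 was 1 of these 3 (-1.38), and RARS1 had no other probe set to compare. A shift that depends only on signal level is argued against as well, since in the deposited values removing a smooth curve of deviation on level, which ran from -0.072 to 0.22, left the array's spread (SD) at 0.487, or 1.40 times that of the next array. Defects of single probe sets on that array may be the cause, and no other biological explanation was tested.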

How the results depend on the processing

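KDM1A was lower under each alternative, including those added after seeing the data (array weights, both doubted arrays left out), with log2 fold changes from -1.39 to -1.25. In the 14 alternatives with a test its limma adjusted p over the list alone ran from 3e-05 to 0.0121, and over all genes from 0.0194 to 0.998, past the threshold in 2 of them. Those were the replicate block and the fit without siControl replicate 2 (-1.32, adjusted p = 0.0474). Array weights were equal within each group and could not separate its arrays. The counts of 0 higher and 0 lower genes held under the other scalings, filters, probe set rules and variance priors and at an adjusted p of 0.1. At an unadjusted p under 0.05 with at least a 2-fold difference, limma gave 55 higher and 35 lower genes. The replicate numbers were not shown to pair the arrays, since same-numbered arrays' deviations had a correlation of 0.05 across genes. That check includes siControl replicate 1, which stood apart, and cannot exclude pairing. The BioB hybridization control was higher on both arrays numbered 2 (by 0.82 and 0.77). Setting number 1 against number 2 gave 526 genes at an unadjusted p under 0.05 in limma, against 409 for the real groups. With a replicate block 10 genes were higher and 3 lower, with KDM1A at -1.32 (adjusted p = 0.0194). The block uses up most of the degrees of freedom that 4 arrays leave, so these calls rest almost wholly on spread borrowed from other genes. ISLR2, TWIST1, UNC5B and CD9 were among these higher genes and VHL and GNL3L among the lower, and the block changed the call of no list. Leaving out 1 array at a time, where a lone array is assumed to vary like the other group, gave 0 to 82 higher and 0 to 1 lower genes, 0 to 3 higher and 0 to 4 lower lists, KDM1A from -1.39 to -1.25, a hypoxia list median from -0.0754 to -0.00489 and a fibroblast list median from -0.16 to 0.20. The 82 higher genes appeared without siControl replicate 2, when siControl replicate 1 was the lone control, and were led by RARS1 and USP48, which are low on that array alone, and included CD9, TWIST1, GSR, PEPD and PAK1IP1. The lower gene was KDM1A there and FOLR1 without siLSD1 replicate 1. Without siControl replicate 1, 3 lists were higher and 4 lower, the hypoxia list turned to -0.0754 and the fibroblast list to 0.19, and without siControl replicate 2, 0 lists were higher. The count of higher lists was 1 without a filter, 1 with the mean of all probe sets and 1 with every probe set by itself (the mesenchymal list each time), and 0 with an estimated correlation and 0 with fry. Among values without a call, and over the alternatives that can move them apart from median centring, the sign changed in 50 of 203 list medians, in 31 of 823 values of named genes and in 1 of 164 values of the 24 genes named from the whole array. The median log2 fold change of all genes was 0.0068, 0.0072 under the deposited scaling and -0.07 under median centring, which shifts every fold change from the deposited scaling by the same -0.0756. Offsets before the logarithm were planned for linear values and do not apply. Except where fewer arrays or another test are the alternative itself, the cause was not tested. Dim signal and the number of arrays limit what could be seen.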

Other observations

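The tests on the gene lists and on other splits of the arrays were chosen after the results were seen.

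The mesenchymal and TGF-beta lists were the only ones camera called with all 4 arrays, a preset correlation and the chosen scaling, filter and probe sets. Both calls were lost without siControl replicate 2, and the TGF-beta call also without siLSD1 replicate 2 (median 0.13, adjusted p = 0.35), without a filter and under both other probe set rules. A low level of these genes on siControl replicate 2 alone is a candidate explanation for the mesenchymal list, whose median without that array was 0.0931 in place of 0.26. Leaving out the lower control array shrinks an upward difference whatever its cause, so this fall does not test the explanation. Genes that move together between arrays of one group may also account for both calls. The estimated correlation was 0.19 within the TGF-beta list and 0.34 within the mesenchymal list. Neither list was called with an estimated correlation, but that loss cannot be assigned to genes moving together. In that setting camera takes its degrees of freedom from the 4 arrays and not from the genes, so a list could hardly pass. Camera's unadjusted p also rose in every list whose estimated correlation was negative. It went from 0.0343 to 0.149 for cholesterol biosynthesis (-0.041) and from 0.0271 to 0.131 for axon guidance (-0.024). Without siControl replicate 1 the mesenchymal median was 0.46 and the TGF-beta median 0.29, and both lists stayed called. There, however, the fibroblast markers, which share 3 genes with the mesenchymal list, were called higher too (0.19) and 4 other lists lower. An effect of LSD1 siRNA on these genes thus stays open and cannot be judged from arrays that differ within their groups.

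Both siLSD1 arrays had a higher signal than both siControl arrays for CD9, a tetraspanin of the cell surface, with values of 4.11 and 6.97 on the siControl arrays and 7.89 and 7.95 on the siLSD1 arrays. Its log2 fold change of 2.38 did not pass the threshold in limma (adjusted p = 0.9996), and the gene was picked out after its values were seen. CD9 passed in limma with a replicate block (adjusted p = 0.0194), a fit that rests almost wholly on spread borrowed from other genes. It did so although the rise was much smaller between the arrays numbered 2 than between those numbered 1. The log2 fold change of CD9 was 3.81 without siControl replicate 2 and 0.95 without siControl replicate 1, and its other probe set above the filter gave 0.23.

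The 4 arrays can be parted into 2 and 2 in 3 ways, which are too few for a share under 0.05. The real split gave 409 genes at an unadjusted p under 0.05 in limma, the highest of the others 526, and 3 of the 3 gave as many as the real one. The split with 526 genes set replicate number 1 against number 2, and the BioB hybridization control was higher on the arrays numbered 2, by 0.82 among the siControl and by 0.77 among the siLSD1 arrays.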
